A study of Mus musculus with 6 samples.

How the data were processed

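Gene expression was measured with Illumina bead arrays in mouse E14 embryonic stem cells that expressed Snail-ER, a fusion of the zinc finger repressor Snail (Snai1) to an estrogen receptor domain. The labels state that 4-hydroxytamoxifen (4-OHT) was given so that the fusion enters the nucleus. The cells were kept in serum and LIF, a cytokine that maintains the undifferentiated state. The 6 arrays covered 0, 2, 4, 8, 12 and 24 h of 4-OHT, with 1 array per time. Array, time and group were taken from the sample titles. The labels do not say whether the arrays came from separate cultures, and no array of untreated cells kept for the same hours, or of cells without the fusion, was analysed here. Time in culture, 4-OHT and the fusion therefore change together in every comparison.

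The authors deposited 2 tables. The first holds, for each probe and array, the probe intensity on a linear scale without background subtraction, and a detection p-value, per the file headers. The detection p-values were multiples of the share of 936 negative controls brighter than the probe, as judged from the values. The second, deposited as the series' value table, holds normalized intensity for 45281 probes. The submitters' processing notes name GenomeStudio, with no version, and the steps were not given in the sources used here. From the values, the normalized table is linear, background-subtracted, not centred by gene and quantile normalized. Its minimum of -17.659 and its maximum of 32363 were the same on all 6 arrays, its medians were 4.71, 4.73, 4.75, 4.72, 4.77 and 4.77 in order of time, and on each array its probe ranks matched those of the first table (Spearman correlation 1). How the background was subtracted remains unknown.

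The first table, called the signal table here, as held for this work covers 32765 probes, 72.4% of those in the normalized table. It is ordered by symbol and stops early. It covers 97.3% of the probes whose gene symbol starts with A to N and 20.8% of those starting with P to Z. The planned fits were kept on the signal table. Genes outside it, among them Snai1, Pou5f1, Sox2 and Vim, were analysed from the normalized table and are named as such wherever they appear. That use of the normalized table was chosen after the data were examined.

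Signal table intensities were background-corrected with limma 3.58.1 in R 4.3.3, by normexp with the background mean and SD inferred from the detection p-values and an offset of 16, then quantile normalized and put on the log2 scale. Normalized table values were set to 0 where negative, and 16 was added before log2. Folds on both scales understate changes of dim genes. Probes with a detection p under 0.01 on at least 1 array were kept. For the normalized table, which has no detection p, a probe was called detected where it reached the lowest normalized signal of a detected probe on that array. Gene symbols came from the platform annotation of the probes, checked by Entrez identifier against the RefSeq genes of GRCm38.p6. Of the probes, 34885 had 1 gene symbol, 18 had several and 10378 had none, and 34807 matched RefSeq. Probes with several symbols or none were left out of the gene analyses. Of several probes per gene, the one with the highest mean over the 6 arrays was used, a choice blind to time. This left 6137 genes in the signal table and 9432 in the normalized table, of which 3037 were outside the signal table. No coordinates are given because the array tables name no genome build.

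With 1 array per time, genes at least 2-fold from the 0 h array were counted without a test, among genes detected on at least 1 of the 2 arrays compared. Where a gene was detected on only 1 of them, the fold is given as "at least", against the higher of its own signal and the lowest signal of a detected probe on the other array. Tests rested on the scatter among the 6 arrays. For a trend over time, the log2 signal was fitted against log2(hours + 1) with limma's lmFit and eBayes with an intensity trend, 2-sided, with 4 residual degrees of freedom and Benjamini-Hochberg adjustment at 0.05. The fitted change is the slope times the span from 0 to 24 h and carries its standard error (SE). Its p-values measure the scatter of single arrays about the line, which may be technical. Words such as rose and fell are used of genes and lists past this test. A second limma fit set each array in turn against the other 5.

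Before the data were examined, 23 gene lists were fixed, with 399 different genes, of which 149 were measured in the signal table and 233 in the normalized table. The lists were naive pluripotency, general pluripotency, primed epiblast, primitive endoderm, trophectoderm, mesoderm and primitive streak, neuroectoderm, epithelial junctions, mesenchymal, retinoic acid response, estrogen response, cholesterol synthesis, immediate early and heat shock, G2 and M phase, p53 targets, 2-cell-like, hypoxia and glycolysis, amino acid and ER stress, fibroblast feeder markers, LIF and STAT3 targets, Wnt targets, FGF and ERK targets, and TGF-beta and BMP targets. Each list was tested on the trend with limma's camera, with a preset correlation between genes of 0.01 and also with an estimated one, adjusted over the lists. At each time, its median log2 difference from 0 h was set among 10000 random lists of the same size, matched on mean expression in 20 bins. For the tests of background noise, 10000 sets of other genes were drawn, each gene from the 50 nearest in the dimmer of its signals on the arrays that defined the set.

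The genes named were also chosen by a rule fixed before the data were examined. It takes the 10 largest rising and 10 largest falling slopes past the threshold. It takes the 5 largest differences each way at 4 h among genes at least 1.5-fold apart at both 2 and 4 h, and the 10 largest each way at 24 h among those at least 1.5-fold apart at both 12 and 24 h, in both cases detected on both arrays compared. It takes up to 3 genes each way that differed at 4 and 8 h and lay within 1.2-fold of 0 h at 24 h, up to 4 members of each list, and 14 genes of the study's subject. Genes known only by clone or model identifiers were counted and not named. The rule was applied to the signal table and again to the genes outside it.

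The trend fit was tested on simulated data for the 6137 genes, with 50 genes changed at each size. It recovered 24% of changes of 0.5 on the log2 scale, 62% of changes of 1, and 100% of changes of 2 and of 3, with 7 false calls. In the simulated test of the lists, the 1 shifted list was called and no unshifted list was. The simulated noise was independent between genes, so this test does not cover lists whose genes vary together. In the data the estimated correlation was 0.55 for naive pluripotency, 0.47 for trophectoderm and 0.30 for hypoxia and glycolysis. The alternatives tried were the normalized values for the same probes or for all probes, no background correction, median scaling, other detection filters, a 1.5-fold threshold, the 2 h array as baseline, the mean of a gene's probes, other time scales, a constant prior variance, an estimated correlation between genes and each array left out in turn. Of these, all probes of the normalized table was added after the data were examined. The number of arrays and, for dim genes, the background of each array limit the precision. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.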

Results

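The series followed E14 mouse embryonic stem cells with Snail-ER over 24 h of 4-OHT, on 1 array each at 0, 2, 4, 8, 12 and 24 h. The question was how expression changes with time after nuclear entry of the Snail fusion is induced. There were no replicates, so differences from 0 h carry no error, and the tests rest on the scatter among the 6 arrays. In order of time, 7002, 6561, 8844, 6885, 10531 and 10472 probes were detected, and the background SD was 16.1, 14.7, 8.72, 15.99, 4.72 and 4.73 intensity units. The 0, 2 and 8 h arrays thus had the widest backgrounds. The correlation of each later array with the 0 h array, across genes, which are not independent replicates, was 0.988, 0.987, 0.965, 0.959 and 0.959. The first principal component held 60.6% of the variance and ran from -22.8 at 0 h, -16.6 at 2 h and -11.1 at 4 h to 13.1 at 8 h, 18.6 at 12 h and 18.8 at 24 h.

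The probes of the construct's own genes were examined first. In the normalized table, 1 of 2 Snai1 probes was detected, with normalized signals of 84.9, 55.2, 47.9, 23.4, 18.6 and 19.8 in order of time. It was below detection at 2 and 8 h, and its fitted change was -1.71 ± 0.29 (SE, log2; limma adjusted p = 0.0068). No Esr1 probe was detected on any array. Where these probes lie relative to the transgene is not known here, and 4-OHT acts on the location of the fusion protein, so these values neither check the labels nor measure the fusion.

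The largest rises with time were in genes that were dim or undetected in the first hours. Acta2, smooth muscle actin, was not detected up to 4 h and was at least 7.88-fold higher than at 0 h by 8 h and at least 13.2-fold higher at 24 h (limma adjusted p for the trend = 0.0074). Igf2, an imprinted growth factor gene, was at least 9.59-fold higher at 24 h, and the Wnt receptor gene Fzd2 at least 5.06-fold. The carbonic anhydrase gene Car4 was at least 4.96-fold higher, and Fgf5, a marker of the epiblast after implantation, at least 3.01-fold. The homeobox gene En1, also undetected up to 4 h, was at least 2.997-fold higher. Anxa3, Igdcc4, Miat and Chst1 completed the 10 steepest rises, and Igdcc4, detected on all 6 arrays, was 4.08-fold higher at 24 h. Among genes detected throughout, Ccn2, which encodes a matricellular protein, was 1.97-fold higher at 4 h and 7.05-fold higher at 24 h (fitted change 2.60 ± 0.27; limma adjusted p = 0.0025). Id1, an inhibitor of basic helix-loop-helix factors, was 5.21-fold higher at 24 h, and Cdkn1c, an imprinted inhibitor of cyclin-dependent kinases, 5.07-fold. Car2, Lpar4, Fgfr2, Map7d3, Lmo4 and Gnas rose as well, with 24 h values from 2.83-fold for Gnas to 3.63-fold for Car2. Outside the signal table, normalized values rose for the POU factor gene Pou3f1 (6.25-fold at 24 h), Sall2 (4.45-fold), Lpar6 (4.37-fold), Zfhx3 (3.37-fold), Zyx (3.01-fold) and the collagen chaperone gene Serpinh1 (2.97-fold).

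Among the largest falls, Cldn4, a tight junction claudin, was 2.51-fold lower at 4 h and 11.3-fold lower at 24 h (fitted change -3.71 ± 0.50; limma adjusted p = 0.0042). The receptor tyrosine kinase gene Kit was 2.17-fold lower at 4 h and 5.83-fold lower at 24 h (-3.16 ± 0.48; limma adjusted p = 0.0053). Klf2 was 5.25-fold lower at 24 h, the helix-loop-helix repressor gene Bhlhe40 5.76-fold, Dnajc6 5.16-fold, Mras 5.01-fold, and Bmp4, which encodes a secreted signal, 4.83-fold. The integrin gene Itgb7 was at least 6.29-fold lower at 24 h, Ly6g6e at least 4.98-fold and Tprg at least 4.95-fold. Pdk1, an inhibitor of pyruvate dehydrogenase, was 5.55-fold lower, Ier3 4.99-fold and Notum, a secreted Wnt antagonist, 4.98-fold. Normalized values outside the signal table fell for Wfdc2 (5.99-fold lower at 24 h), Tcl1 (5.58-fold), Tfcp2l1 (5.25-fold), Rmnd5b (4.21-fold), Smtnl2 (4.12-fold), Ano9 (3.87-fold) and Zfp42 (3.86-fold).

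In total 375 genes rose and 393 fell, of 6137 tested, by limma at an adjusted p of 0.05. Among the 3037 genes outside the signal table, 186 rose and 172 fell in the normalized values. Of 270 called genes with several kept probes, 240 had all probes sloping the same way and 30 did not. Left-out arrays moved these counts: 140 rose and 141 fell without the 0 h array, 189 and 224 without the 2 h array, 94 and 112 without the 12 h array, and 190 and 228 without the 24 h array. Against untransformed hours only 12 rose and 5 fell. Of the 71 named genes with a call, 38 lost it without at least 1 of the arrays and none changed sign.

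**Figure D1:**
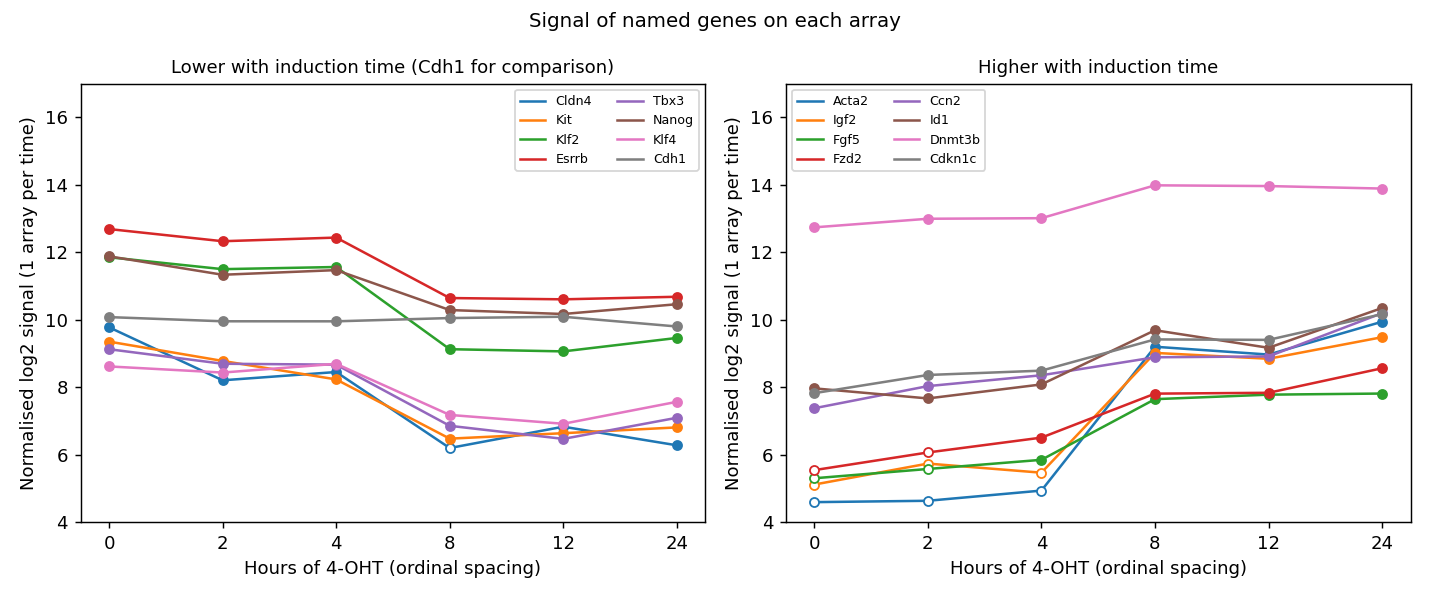
Normalised log2 signal of 16 named genes on each array, against hours of 4-OHT on an ordinal axis, with 1 array per time. Filled points are detected and open points are not. Most falling genes step down between 4 and 8 h, whereas the Cdh1 probe shown, the brighter of its probes, stays near its 0 h signal.

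Genes at least 2-fold from 0 h were counted at each time. At 2 h, 28 genes were higher and 48 lower than at 0 h, and at 4 h, 6 were higher and 66 lower. At 8 h the counts were 128 and 231, at 12 h 175 and 262, and at 24 h 189 and 252. Between neighbouring times, 76 genes differed from 0 to 2 h, 49 from 2 to 4 h, 235 from 4 to 8 h (85 up and 150 down), 71 from 8 to 12 h and 20 from 12 to 24 h. Many of these genes were near background. Among genes detected on both arrays, 1 was higher and 8 lower at 2 h, 0 and 18 at 4 h, 41 and 106 at 8 h, 57 and 197 at 12 h, and 64 and 184 at 24 h. The excess of lower genes at 24 h was not seen in the normalized values of the same probes, where 266 were higher and 258 lower. At 8 h it was seen there, with 120 higher and 233 lower. Without background correction 33 were higher and 79 lower at 24 h.

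**Figure D2:**
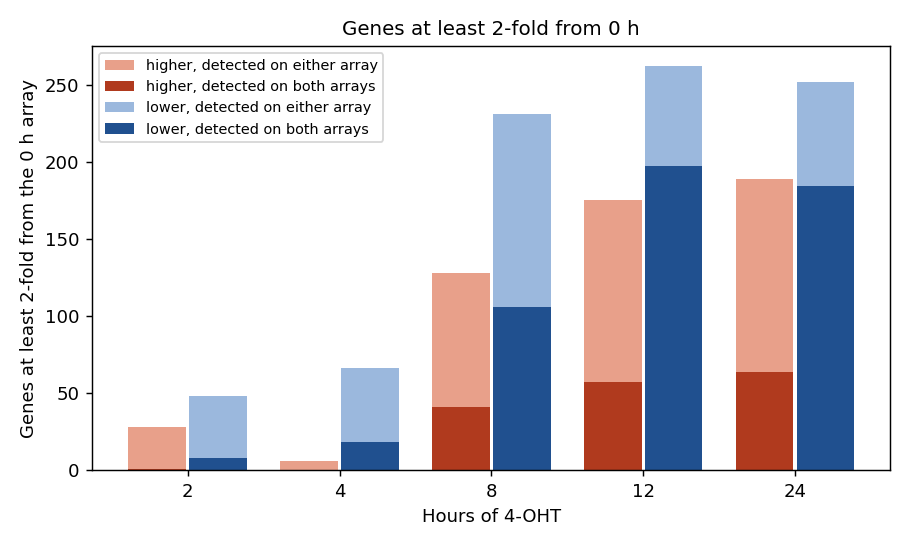
Number of genes at least 2-fold higher (red) or lower (blue) than on the 0 h array at each time, with 1 array per time. Dark bars count genes detected on both arrays and lie in front of pale bars that count genes detected on either, such as 64 and 189 higher genes at 24 h.

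By the rule for early change, Ccn2 led the higher genes, followed at 4 h by Dapk3 (1.71-fold), Ccdc85b (1.65-fold), Meis2 (1.59-fold) and Metrn (1.58-fold). Of these, Ccn2 and Metrn rose over the series (limma adjusted p = 0.045 for Metrn), and Dapk3, Ccdc85b and Meis2 did not pass (limma adjusted p = 0.20, 0.20 and 0.084). Outside the signal table, normalized values at 4 h were higher for Pou3f1 (1.60-fold), 1 probe of Sox2 (1.55-fold) and Trappc3 (1.51-fold), and lower for Vash2 (4.42-fold) and Rmnd5b (2.74-fold), among others. The largest early lower genes of the signal table were Stum (3.47-fold lower at 4 h), Misp (3.19-fold), Fech (3.14-fold), Glt1d1 (3.10-fold) and Toporsl (2.99-fold). At 8 h, on an array with a wide background, Stum, Glt1d1 and Toporsl lay 0.71, 0.30 and 0.36 below 0 h on the log2 scale, closer to 0 h than at 4 h. Glt1d1 and Toporsl did not pass the trend test (limma adjusted p = 0.058 and 0.086). The genes that differed at 4 and 8 h and were back at 24 h, Ccdc121, Bicdl2, Simc1 and Ankrd33b, were each undetected at 0 h. Ccdc121 and Bicdl2 were detected only at 4 h, so their differences at 8 h lie between signals that were not detected.

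The limma fit of the 0 h array against the 5 induced arrays called 0 genes, with 497 at an unadjusted p under 0.05 and a smallest adjusted p of 0.23. The normalized values of the same probes also gave 0. The spread in this fit includes the differences among the later times, so the count says little about whether the 0 h array stands apart. Of the other arrays taken alone, the 2 h array gave 1 gene and the rest 0.

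Naive pluripotency genes, which mark the ground state of mouse embryonic stem cells, fell as a group. Of 14 measured members, 10 fell and none rose (11 fell when adjusted over the list alone; camera adjusted p = 9.49e-08). This call was lost with an estimated correlation between genes (adjusted p = 0.51). The list's median difference from 0 h was -0.18 at 2 h, -0.25 at 4 h, -1.41 at 8 h, -1.53 at 12 h and -1.09 at 24 h on the log2 scale. Against the 2 h array the 4 h median was 0.02. The middle 95% of random lists at 24 h ran from -0.20 to 0.24. Klf2 was 5.25-fold lower at 24 h, Tbx3 4.09-fold, Esrrb 4.02-fold and Nanog 2.68-fold, with a fitted change for Nanog of -1.78 ± 0.32 (SE; limma adjusted p = 0.0088). Klf4 (2.07-fold lower) and Nr5a2 (2.18-fold lower) also fell. Prdm14, another of the 10, was detected only at 4 h, so its fall lies largely between signals that were not detected. Gbx2 was 1.64-fold higher at 24 h and did not pass. By normalized values, 13 of 17 members fell, with Tfcp2l1, Tcl1 and Zfp42 among them.

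General pluripotency genes showed no shared trend over the series. Kit was the 1 of 9 measured members that fell, and none rose (2 rose and 3 fell when adjusted over the list alone; camera adjusted p = 0.87). Their median at 2 h was -0.18, like that of the naive list, at percentile 1.42 of the random lists. At 24 h it was 0.14, at percentile 85.9. By normalized values the 2 h median was -0.053, at percentile 12.8, and the 24 h median 0.17, at percentile 97.3. Of 17 members there, Utf1 rose and 2 fell, Tcea3 among them (camera adjusted p = 0.98). Lin28a was 1.71-fold higher at 24 h and Eras 1.60-fold lower, and neither passed (limma adjusted p = 0.11 and 0.087). In the normalized table, Pou5f1, the gene for OCT4, had a fitted change of 0.49 ± 0.18 (limma adjusted p = 0.10) and Sox2 of 0.42 ± 0.29 (limma adjusted p = 0.36). The other Sox2 probe had a normalized signal of 249 at 0 h and 214 at 24 h, so the probes of Sox2 differ in direction.

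Primed epiblast genes, which mark the later state that follows the naive one, lay above the random lists at 24 h, with a median of 1.15. Of 5 measured members, 3 rose and none fell (4 rose and 1 fell when adjusted over the list alone), and the list did not pass camera in the signal table (adjusted p = 0.079, and 0.51 with an estimated correlation). Fgf5, Lef1 and the DNA methyltransferase gene Dnmt3b rose, with Dnmt3b 2.22-fold higher at 24 h and Lef1 at least 2.37-fold. Cldn6 was 1.76-fold lower and did not pass (limma adjusted p = 0.063). By normalized values, 6 of 9 rose, among them Pou3f1 (camera adjusted p = 5.91e-04, and adjusted p = 0.67 with an estimated correlation).

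Of 6 measured trophectoderm genes, 5 rose (5 also adjusted over the list alone; camera adjusted p = 3.46e-04, and adjusted p = 0.51 with an estimated correlation). They were Id2, at least 4.54-fold higher at 24 h, Fgfr2 at 2.97-fold, the keratin genes Krt8 at 2.03-fold and Krt18, and Eomes. Krt18 and Eomes were detected only at 12 and 24 h, the arrays with the lowest backgrounds. Id2 is also a BMP target and Krt8 and Krt18 belong to simple epithelia in general. The trophectoderm regulator Cdx2 was not detected on any array. Tfap2c, another member, fell in the normalized table.

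Hypoxia and glycolysis genes fell, with 6 of 9 measured members falling and none rising (6 adjusted over the list alone; camera adjusted p = 3.51e-04, and adjusted p = 0.51 with an estimated correlation). Pdk1 led the list, followed at 24 h by the aldolase gene Aldoc (3.65-fold lower), Ankrd37 (3.31-fold) and Ndrg1 (2.01-fold). The median was -0.13 at 4 h, -0.90 at 8 h and -0.97 at 24 h. By normalized values, 8 of 16 members fell, and the medians were smaller, at -0.08, -0.56 and -0.52.

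**Figure D3:**
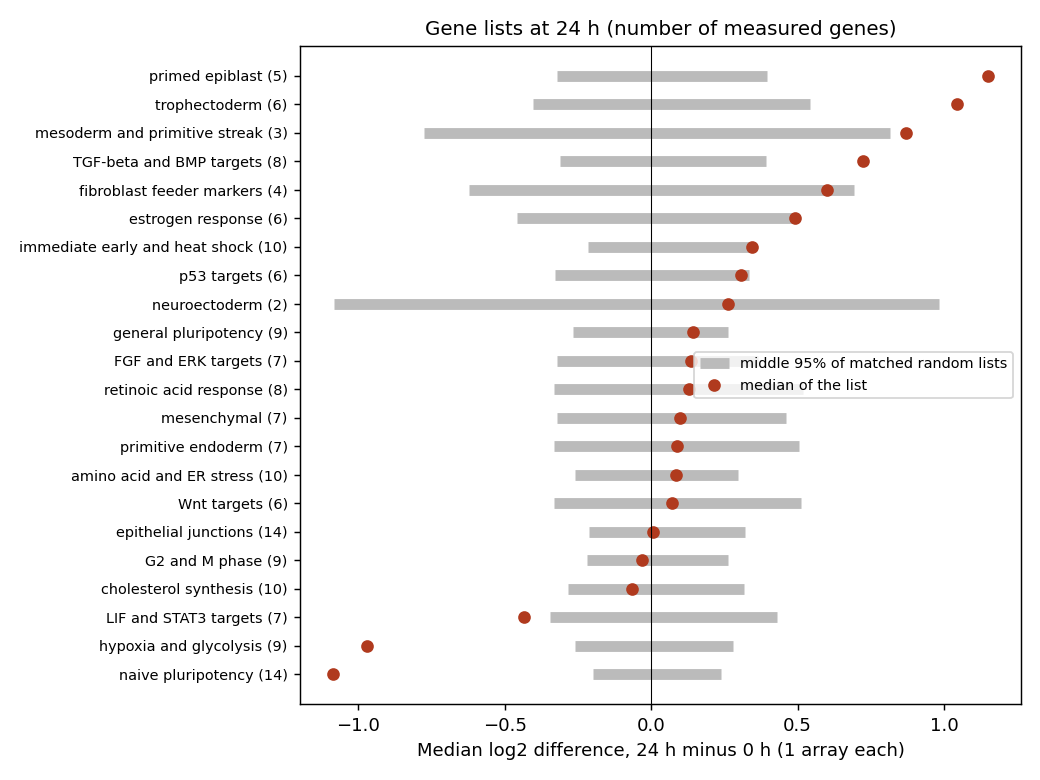
Median log2 difference between the 24 h and 0 h arrays for each list with at least 2 measured genes (red points; the number measured is in parentheses), with grey bars for the middle 95% of expression-matched random lists. Naive pluripotency at -1.09 and primed epiblast at 1.15 are the extremes.

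Epithelial and mesenchymal genes, the classes that Snail is best known to regulate, did not pass the list test. Among 14 measured epithelial junction genes, 3 rose and 2 fell (3 and 3 adjusted over the list alone; camera adjusted p = 0.73). Cldn4 fell, and so did the polarity gene Llgl2 (2.11-fold lower at 24 h), while Krt8, Krt18 and Grhl2 rose. Cdh1, which encodes E-cadherin and is a known target of Snail repression, had a fitted change of -0.15 ± 0.15 (SE; limma adjusted p = 0.55). Its log2 differences from 0 h were -0.12, -0.12, -0.03, 0.01 and -0.28 in order of time. A dimmer Cdh1 probe, detected at 0, 4, 12 and 24 h, was lower after 0 h, with normalized signals of 73.85, 39.81, 49.24 and 45.43 at those times. Over the 23 epithelial junction genes of the normalized table, 3 rose and 3 fell (camera adjusted p = 0.10). Their median was -0.24 at 4 h and -0.22 at 24 h, at percentiles 0 and 0.83 of the random lists, and 0.0055 at 12 h, at percentile 21.5. Among 7 measured mesenchymal genes, 2 rose and 2 fell (2 and 2 adjusted over the list alone; camera adjusted p = 0.89). Acta2 and the membrane metalloproteinase gene Mmp14 (2.21-fold higher at 24 h) rose. Fibronectin, Fn1, fell (2.73-fold lower) and so did N-cadherin, Cdh2 (at least 2.15-fold lower). Vim, which encodes vimentin, rose in the normalized table, at 2.46-fold at 24 h (1.25 ± 0.24; limma adjusted p = 0.011). Over its 13 mesenchymal genes, 4 rose and 2 fell (camera adjusted p = 0.54), and the median was 0.55 at 24 h, at percentile 99.8, and -0.06 at 12 h, at percentile 13.5.

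Signalling lists gave mixed results. Of 8 measured TGF-beta and BMP targets, 4 rose and 1 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.80). Id1 rose, Id2 rose, Id3 was at least 3.42-fold higher at 24 h and Msx1 rose, while the Nodal antagonist gene Lefty2 fell. Msx1 was detected only at 12 and 24 h, the arrays with the lowest backgrounds. The median of these targets at 24 h was 0.72, at percentile 99.98 of the random lists, but 0.35 by normalized values, at percentile 93.4. Of 7 LIF and STAT3 targets, 3 fell and none rose (camera adjusted p = 0.15), namely Icam1 (3.08-fold lower at 24 h), Klf4 and Klf5, of which the Klf genes are also members of the naive list. Adjusted over the list alone, 1 rose and 3 fell. The LIF and STAT3 median was -0.92 at 8 h and -0.89 at 12 h, both at percentile 0.02 of the random lists, and -0.43 at 24 h, at percentile 1.09. By normalized values 5 of 13 fell and none rose (camera adjusted p = 0.012, and 0.67 with an estimated correlation). Tfcp2l1, also a member of the naive list, was among those that fell, so this result is not separate from the naive fall. Of 6 Wnt targets Lef1 rose and Notum fell, in both adjustments (camera adjusted p = 0.89). Of 7 FGF and ERK targets, Egr1 rose, and Ier3 and Etv5 fell, in both adjustments (camera adjusted p = 0.81). None of 8 retinoic acid response genes passed in either adjustment (camera adjusted p = 0.89), and Meis2 had the largest difference at 24 h, 2.72-fold higher. Of 6 estrogen response genes, a list fixed because 4-OHT binds estrogen receptors, Cxcl12 and Greb1 rose in both adjustments (camera adjusted p = 0.079). Greb1 was detected only at 4, 12 and 24 h, the arrays with the narrower backgrounds. Of 8 estrogen response genes in the normalized table, 2 rose and 1 fell (camera adjusted p = 0.54). The falling gene was Pdzk1, with a fitted change of -1.86 ± 0.45 (limma adjusted p = 0.025).

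Among lists of other cell fates, Fst rose and Lama1 fell of 7 primitive endoderm genes (2 and 1 adjusted over the list alone; camera adjusted p = 0.89), and Gata6 was not detected on any array. Fst was detected only at 12 and 24 h. Eomes was the 1 of 3 mesoderm genes that rose (2 adjusted over the list alone; camera adjusted p = 0.66). The mesoderm median at 24 h was 0.87, at percentile 98.3 of the random lists, but none of the 3 was detected at 0 h. By normalized values it was 1.08, at percentile 99.8, with 2 of 5 rising (camera adjusted p = 0.39). Neither of 2 measured neuroectoderm genes passed in either adjustment (camera adjusted p = 0.81). Of 4 neuroectoderm genes in the normalized table, Sox11 rose (fitted change 1.92 ± 0.23; limma adjusted p = 0.0030), and the list did not pass (camera adjusted p = 0.39). Of 4 fibroblast feeder markers, Loxl1 rose (2 adjusted over the list alone; camera adjusted p = 0.63), and Dcn was detected only at 12 and 24 h, the arrays with the lowest backgrounds. Loxl1 was detected only at 4, 12 and 24 h.

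Lists of cell state included 6 p53 targets, of which Mdm2, Aen and Ccng1 rose in both adjustments (camera adjusted p = 0.47). Aen was detected only at 12 and 24 h. The p53 median was 0.63 at 12 h, at percentile 99.93 of the random lists, and 0.31 at 24 h, at percentile 96.36. By normalized values 5 of 12 rose and none fell (camera adjusted p = 0.020, and 0.68 with an estimated correlation). None of 9 G2 and M phase genes passed in either adjustment (camera adjusted p = 0.89). Of 10 cholesterol synthesis genes Ebp fell (2 fell adjusted over the list alone; camera adjusted p = 0.47). Of 10 amino acid and ER stress genes Ddit4 fell in both adjustments (camera adjusted p = 0.89). Their median was 0.33 at 12 h, at percentile 98.1 of the random lists, and 0.08 at 24 h, at percentile 71.65. Chac1 was at least 3.45-fold higher at 12 h and did not pass the trend test (limma adjusted p = 0.18). Among 10 immediate early and heat shock genes, Egr1 rose and Ier3, Dusp1 and Gadd45b fell (2 and 3 adjusted over the list alone; camera adjusted p = 0.89). Gadd45b was detected only at 4 h, so its fall lies largely between signals that were not detected. No 2-cell-like gene was measured in the signal table.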

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

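All tests in this part were chosen after the pattern they bear on had been seen, except the count over other orders of the arrays. The noise tests that use matched sets of other genes replaced earlier versions that had already been run.

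Probes that the annotation used here does not name also followed time. Of 2167 such probes detected on at least 1 array, 215 passed the limma trend test, 112 rising and 103 falling. They stand out because the gene comparisons leave them out, and no explanation was tested.

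The first pattern is the genes lower than at 0 h, whose excess at 24 h lay among genes detected on both arrays, with 64 higher and 184 lower, whereas 125 higher and 68 lower genes were detected on only 1. The lowest signal of a detected probe was 6.22 at 0 h and 5.15 at 24 h on the log2 scale. A falling gene could thus stay detected at 24 h at a signal undetected at 0 h, so unequal detection can shape this split. At 8 h, where the lowest was 6.27, lower genes led in both classes (41 higher and 106 lower, 87 and 125). The 0, 2 and 8 h arrays have wide backgrounds. Some dim probes may thus read higher on all of them than on the others, called shared noise here. Genes as a whole did not read higher, with a median 8 h minus 12 h of -0.048. The 66 genes lower at 4 h were brighter at 8 h than at 12 h by a median of 0.71 on the log2 scale (quartiles 0.18 and 1.34). Shared noise is thus a candidate explanation for them. For all 252 genes lower at 24 h the same median was 0.092 (quartiles -0.15 and 0.40), where shared noise was taken to need 0.58. Noise of the 0 h array alone need not raise the 8 h signal, so this median cannot test it. From 2 to 12 h, arrays that did not define the set, these 252 genes were lower by a median of 0.93 (quartiles 0.49 and 1.36). The middle 95% of sets of other genes matched on the dimmer signal ran from -0.20 to -0.089. Noise of the 0 h array alone would not set the 252 genes apart there. These values together argue against either noise as the whole cause at 24 h.

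The second pattern is the step between 4 and 8 h, for which noise of the 8 h array was tested on arrays outside the step: from 2 to 12 h 77.9% of the 235 genes moved in the direction of the step, by a median of 0.98 (quartiles 0.35 and 1.52), against -0.10 to 0.038 for sets of other genes matched on the dimmer signal. The 77.9% was the earlier test of noise for these 235 genes, and it had left noise open. The median against matched sets was put in its place afterwards. For the 61 that stepped down and were detected on both arrays the median was 1.32 (quartiles 1.09 and 1.72, matched sets -0.17 to 0.039). Both medians argue against that noise as the whole cause, on a test chosen after an inconclusive one. For the 31 that stepped up and were detected on both it was 1.28 with quartiles of -0.28 and 1.51, and noise and a real rise cannot be told apart for them. An offset between a batch of 0 to 4 h arrays and a batch of 8 to 24 h arrays could also give the step, and would leave no common direction within either batch. Of the 235 genes, 41.7% moved the same way as at the step from 12 to 24 h, which the offset allows, and 61.7% from 0 to 2 h. For the 61 that stepped down it was 29.5% and 73.8%, a common direction in each interval, which an offset alone would not give them. For the 31 that stepped up it was 54.8% and 48.4%. Each interval compares 2 single arrays, so an offset stays open for the step as a whole. The labels give no batch, the supposed batches hold different times, and a response to Snail-ER, to 4-OHT or to time in culture stays open beside the offset.

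For the trend, the third pattern, of 100 orders of the 6 arrays, the real one included, 2 gave at least the 768 genes of the real order, and the highest other gave 769. A count this high was thus rare among the orders drawn, which argues against chance order as its source. It does not single out the real order. The 11 other orders that kept the 0 to 4 h arrays and the 8 to 24 h arrays together gave between 0 and 769 genes, with 0 in 6 of them, and orders that mixed them gave at most 0. The count thus needs the early and late arrays apart. The 6 orders with 0 genes ran from early to late arrays but moved the 0 h array off the earliest time. Giving the arrays, in their real order, times of 0, 4, 2, 24, 12 and 8 h or of 0, 2, 4, 12, 24 and 8 h left it there. These gave 599 and 769 genes. Orders that ran from late to early arrays gave 390 genes with the 0 h array placed at 24 h, 212 with it at 12 h and 11 with it at 8 h. The count thus varied with the place of the 0 h array, a single array, but did not need it at either end. These orders cannot decide how much an offset between batches contributed, and an offset remains open for the count.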

How the results depend on the processing

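The all-probe normalized table was added after the data were examined, and the other alternatives were fixed before. Unless stated, the cause of a change was not tested. Detection in dim genes was limited by the wide backgrounds at 0, 2 and 8 h. The all-gene median shift from 0 h stayed under 0.1 in each scaling.

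Counts of 2-fold higher and lower genes moved as follows. Without background correction, which compresses folds, they were 1 and 2 at 2 h, 0 and 7 at 4 h, 19 and 72 at 8 h, 26 and 84 at 12 h, and 33 and 79 at 24 h. At 1.5-fold they were 76 and 130, 155 and 158, 396 and 488, 761 and 545, and 708 and 578 in order of time, with fewer lower than higher genes at 12 and 24 h. With detection on both arrays, which tests fewer genes, 1 was higher and 8 lower at 2 h, 0 and 18 at 4 h, 41 and 106 at 8 h, 57 higher at 12 h and 64 higher at 24 h. With no filter 45 were higher at 2 h and 111 lower at 4 h. Higher genes at 4 h numbered 13 in the normalized values of the same probes, 2 with median scaling, and 10 against the 2 h array, with 39 lower. When all probes of the normalized table were used, 17 were higher at 4 h, 392 at 12 h and 374 at 24 h.

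Trend counts ranged from 94 to 358 rising and from 112 to 436 falling as each array was left out. Hours untransformed gave 12 and 5, and the all-probe normalized table, with more genes, 589 rising. All 768 called genes kept their sign with hours untransformed, where 17 kept the call, and 740 kept it in the normalized values of the same probes. Of the 71 named genes with a call, 62 lost it with untransformed hours, and 17 lost it in at least 1 of the other settings apart from left-out arrays. The count of 0 genes for the 0 h array was also 0 in the normalized values.

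The naive pluripotency median at 2 h was -0.30 in the all-probe normalized table. At 4 h it was -0.16 without background correction, -0.34 with median scaling, and 0.019, reversed, against the 2 h array. At 8 h it was -1.09 without background correction, -1.29 with the mean of probes and -1.57 in the all-probe table. At 12 h these gave -1.13, -1.30 and -1.73, no filter -1.31, detection on 3 arrays -1.70 and the 2 h baseline -1.24. At 24 h it was -0.91 without background correction and -1.36 in the all-probe table. Against the 2 h array, the 4 h medians of primed epiblast (-0.081) and epithelial junctions (0.0051) also reversed, as did TGF-beta and BMP targets at 24 h with no filter (-0.024). Of 814 other list medians under alternatives, 687 moved by at most 1 SD of the matched random lists, 124 by more, and the 3 named reversed.

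With an estimated correlation 0 lists passed in place of 3: naive pluripotency, trophectoderm, and hypoxia and glycolysis each had an adjusted p of 0.51. They passed in the normalized values of the same probes, without background correction, with median scaling and with each array left out. When all probes of the normalized table were used, 6 lists passed, with primed epiblast (5.91e-04), p53 targets (0.020) and LIF and STAT3 targets (0.012) added. With an estimated correlation none of these 6 passed there, with adjusted p = 0.68 for p53 targets and 0.67 for the others.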

Other observations

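The test in this part was chosen after the list medians had been seen. Naive and general pluripotency genes differed at 24 h: the naive list had a median of -1.09 (14 genes) and the general list of 0.14 (9 genes). The gap of 1.23 on the log2 scale had a 2-sided p of 0.0075 over 100000 permutations of list membership, in which genes are treated as independent. In the normalized table, with 17 genes in each list, the gap was 1.53. The permutation argues only against chance membership of the lists, and the batch offset and time in culture, which the design cannot separate from induction, stay open.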
